A study of Homo sapiens with 15 samples.

How the data were processed

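Gene expression was measured in MCF-7:PF cells, a line of the MCF-7 human breast cancer cells that the labels describe as kept in 1 nM 17β-estradiol (E2) and 5 µM PP2, an inhibitor of the kinase c-Src, in medium stripped of other steroids. Per the labels, the cells of each biological replicate were divided over dishes that received 0.1% ethanol (vehicle), 1 nM E2, 1 µM 4-hydroxytamoxifen (4-OHT), 1 µM fulvestrant (ICI), E2 with ICI or 4-OHT with ICI for 7 days. There were 3 replicates, and so 15 arrays for the 5 treatments. On each array the RNA of a treatment carried Cy3 (1237.5 ng hybridised) and the RNA of the vehicle dish of the same replicate number carried Cy5 (825 ng hybridised). Dyes were not exchanged on any array, and each of the 3 vehicle samples was hybridised 5 times.

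The deposited scanner files hold, per the file headers, the median pixel intensity of each spot and of its local background in each dye, as extracted by Agilent Feature Extraction 10.5.1.1, with no normalization. They also hold the processed intensity of each dye, which the authors' software had corrected for background, spatial trend and dye. The deposited log10 ratio was tested against these values and is Cy5 over Cy3, so its sign was turned. The deposited series table holds log2 values, which equalled the log2 of treatment over vehicle from the scanner's ratio within 1e-06 except at a pair of spots per array, with a median of 0 on every array. The files name human genome build hg18, whereas the gene table used here is of a later build, so no coordinates are given. Genes were named only through the RefSeq accession printed with each probe: 17427 of 18071 accessions matched, and 24794 of 41000 probes received a symbol. The other 16206 probes stayed in the tests under their own accession and were never named.

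Each array had 45015 spots, of which 1639 were controls, and no spot was saturated. The background was removed with the normexp model of limma 3.58.1 with an offset of 50, and each array was normalized by loess of its log2 ratio on intensity with control spots given no weight. Mean signals had been planned, but the files hold medians, which were used instead. Spots marked by the scanner as non-uniform or as population outliers were left out, and repeated spots of a probe were averaged. A probe was kept if it was well above background in Cy3 on all 3 arrays of a treatment or in Cy5 on all 15 arrays, which left 27795 probes. The brightest kept probe stood for each gene. The offset draws the ratios of dim spots towards 0. For a gene that was below background on every array of one side, the report gives no fitted value but, where one was computed, a lower bound. For KLK8 between E2+ICI and E2 the fitted value stands beside the bound. The section on unexpected results prints the fitted values of 3 such genes and names them. The bound was computed on levels of single dyes, which hold the offset. It sets the side with signal against the weakest signal that the scanner called well above background on the other side's arrays. Between treatments the levels are not divided by vehicle, so a bound can exceed the fitted fold.

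One step was changed after a full set of results had been seen. On the array of E2+ICI replicate 3, the spread of log2 ratios over all spots (median absolute deviation) had been 0.033, against 0.182 to 0.260 on the other 14 arrays. Controls aside, a few spots there had extreme local background, up to 202245 in Cy3 against at most 476.5 on the other arrays, and the normexp fit gave a Cy3 background mean of -1303.5. On all arrays the model was therefore fitted without the spots that the scanner marked for non-uniform background, which left 43165 to 44281 of the 45015 spots per array, and then applied to every spot. The spread on that array became 0.227, against 0.252 for the scanner's own ratio. The first version is kept among the alternatives: it had called 3896 genes between E2+ICI and vehicle, where the repaired one called 6463, and it moved no other comparison's count by more than 1.5 times.

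Log2 ratios of treatment over vehicle were fitted with limma over all 15 arrays with 1 term per treatment (prior degrees of freedom 3.73). The 13 comparisons were the 5 treatments against vehicle, 7 differences between treatments and 1 difference of differences. Tests were two-sided moderated limma tests, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05, and a gene past it is here termed called. In ratios to vehicle a probe's dye effect adds to the treatment effect, while in differences between treatments vehicle and dye cancel. The sets of genes were 18 lists fixed beforehand: estrogen-induced ER targets, estrogen-repressed genes, cell cycle, apoptosis regulators, cholesterol biosynthesis, the unfolded protein and integrated stress response, interferon response, growth factor receptor signalling, AP-1 and immediate early genes, luminal markers, basal and mesenchymal markers, NRF2 targets, AHR targets, hypoxia and glycolysis, lysosome and autophagy, ribosomal proteins, and the fibroblast and stromal and the leukocyte and endothelial markers of other cell types. They were tested with camera (preset correlation 0.01), again with an estimated correlation, and with fry, on genes with a value on every array and with adjustment over the lists of a comparison. Of 234 list tests, camera called 96, of which 20 held with an estimated correlation, and fry called 135.

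Same-numbered arrays had residuals that were alike. The correlation across genes of the residual ratios had a median of 0.30 between same-numbered arrays of different treatments, against -0.16 between others, and exceeded 0.1 in 25 of 30 pairs. In the Cy3 level alone it was 0.41 against -0.29. Same-numbered ratios share a vehicle sample, so a positive value is built into them. Residuals were taken from treatment means, so the negative values follow from the positive ones and are no separate yardstick. A fit with the replicate number as a term was therefore run as an alternative, and its counts stand beside those it moved by more than 1.5 times.

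The named genes follow a rule fixed before the data were examined. They are, per comparison, the 5 highest and 5 lowest called genes with a symbol, one sign in all 3 replicates and signal on at least 1 side, then a panel of 12 estrogen-related genes, and up to 4 members of each called list, or the 2 with the smallest p where no member was called. For ratios to vehicle, the highest and lowest genes that were bright in both dyes on all 15 arrays were added after the data had been seen. Errors are standard errors (SE) of the limma fit with n = 3 per treatment. In simulated data with 200 changed genes among 21369, the same steps recovered 79.5% of changes of 0.5 and 97.5% of changes of 1 on the log2 scale in ratios to vehicle, and 43.0% and 93.5% in differences between treatments (E2+ICI against E2). The same simulations also called unchanged genes. In ratios to vehicle (E2) these false calls were 14 beside 159 recovered for changes of 0.5, and 22 beside 195 for 1. In differences between treatments they were 1 beside 86 and 9 beside 187. Their share of calls passed the threshold in ratios to vehicle alone. Counts of genes called against vehicle may therefore hold more false calls than the threshold allows. Larger numbers of changed genes were not simulated. Arrays give no counts, so their number limits the precision.

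The alternatives were no background correction, the scanner's ratio, the authors' series table, median centring in place of loess, scaling between arrays, no filter and a stricter one, the mean of a gene's probes, trend and robust moderation, a replicate block, the slide as a random or fixed block, only the arrays compared, a 2-fold minimum, and leaving out each array and each replicate number in turn. Slide as a fixed block, the first normexp fit and leaving out all spots with marked background were chosen after seeing the data. The computation used R 4.3.3, statmod 1.5.0 and the data.table package in version 1.17.8.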

Results

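Gene expression was measured on 15 arrays in MCF-7:PF cells, a line derived from the estrogen receptor positive human breast cancer line MCF-7 and kept with estradiol and a c-Src inhibitor. The 5 treatments were 17β-estradiol (E2, the natural estrogen, 1 nM), 4-hydroxytamoxifen (4-OHT, the active metabolite of tamoxifen and a selective modulator of the estrogen receptor, 1 µM), ICI (fulvestrant, an antiestrogen that blocks the receptor and lowers its protein, 1 µM) and ICI combined with either of the others, each for 7 days in 3 replicates. The design text gives the purpose as separating regulation by E2 and 4-OHT that depends on the estrogen receptor (ER) from regulation that does not. The labels do not say whether the c-Src inhibitor was present during treatment. Every value is a log2 ratio of a treatment to the vehicle dish of the same replicate, or a difference of such ratios, so vehicle is the background of each measurement.

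Across arrays, 61.4% to 81.5% of probes in Cy3 and 57.9% to 76.6% in Cy5 were well above background, and the median SD of a gene between replicates lay between 0.111 and 0.131 on the log2 scale. The median 95% interval of a gene reached 0.17 on either side of a ratio to vehicle, 0.24 for a difference between treatments and 0.34 for the difference of differences. In all 5 ratios to vehicle, 299 genes were called higher and 258 lower, where independent lists would give 3.72 and 3.38 and simulated unchanged groups that share the vehicle samples gave at most 1 and 2. Few genes are called in such groups, and independent lists leave out the shared vehicle and the shared ICI, so neither sets a baseline. The dyes were never exchanged, so dye and treatment effects cannot be told apart in genes called the same way in all 5 ratios. Large falls against vehicle were often seen where Cy3 was dim: of 203 genes at least 4-fold lower with E2, 36 were bright in both dyes on all arrays, while 9 genes were at least 4-fold higher. A fall can itself make Cy3 dim, so the 36 depends in part on the change. On all 15 arrays, whatever the treatment, 53 of the 203 were dim in Cy3. Loess sets the middle of the ratios near 0 at every intensity, and all changes are relative to it. With median centring in its place the median gene moved to 0.12 with E2, 0.16 with 4-OHT and 0.13 with E2+ICI against vehicle, 0.16 for E2+ICI against ICI, -0.26 for 4-OHT+ICI against 4-OHT, 0.19 for 4-OHT against ICI, 0.13 for E2 against ICI and 0.28 for the difference of differences.

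The first question was what E2 changed against vehicle. The genes that rose most were KLK8, a secreted serine protease (8.40-fold, log2 3.07 ± 0.20 SE, n = 3), AREG, a ligand of the epidermal growth factor receptor (6.75-fold, 2.75 ± 0.07), MYBL1, a transcription factor (2.60 ± 0.10), ENPP2, the enzyme that makes lysophosphatidic acid (2.44 ± 0.17), and GREB1, an ER cofactor (2.34 ± 0.34). TBC1D32, a gene of cilium assembly, fell 8.81-fold (-3.14 ± 0.20) with Cy3 signal on 2 of 3 arrays, and the homeobox gene HOXB2 and the protocadherin PCDHGA2 fell by 2.58 ± 0.14 and 2.41 ± 0.44. F3, which encodes tissue factor, and MEF2C, a transcription factor, were at least 3.68-fold and 4.07-fold lower, as their Cy3 signal was below background with E2. Both were also below background in Cy3 on all arrays with 4-OHT, ICI and E2+ICI, while Cy5 was above it on all 15. The bound sets a Cy5 level against a Cy3 floor, so dye and E2 cannot be told apart in these 2 genes.

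Of the panel of ER-related genes, the secreted trefoil factor TFF1 (RefSeq NM_003225) rose by 1.95 ± 0.30, the progesterone receptor PGR (NM_000926) by 1.27 ± 0.19, IGFBP4 by 1.16 ± 0.15, the chemokine CXCL12 by 0.94 ± 0.05 (with vehicle signal on 1 of 15 arrays), MYC by 0.86 ± 0.07, cyclin D1 (CCND1) by 0.81 ± 0.11 and PDZK1 by 0.77 ± 0.10. The receptor gene ESR1 (NM_000125) fell by 1.36 ± 0.06, with an adjusted p of 6.8e-09 in limma. ESR1 was below 0 and MYC and IGFBP4 above 0 on all 15 arrays, IGFBP4 barely so on E2+ICI replicate 3 (0.004). For these genes a difference by dye may be part of the value. FOS rose by 0.60 ± 0.17, a call that ended without replicate 2 or E2 replicate 2 (0.47) and without E2 replicate 1 (0.61). IGF1R (0.23 ± 0.10) and the proliferation marker MKI67 (0.23 ± 0.09) were not called. The replicate block called both in limma (adjusted p = 0.038 and 0.0056), but these p-values leave out the spread between vehicle samples. TFF1 and GREB1 were lower on the third E2 array (0.76 and 0.70) than on the other two (2.43 and 2.65 for TFF1, 3.14 and 3.17 for GREB1).

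Estrogen-induced ER targets shifted up with E2 (adjusted p = 2.8e-11, camera): 29 of 39 rose and 2 fell, the same counts as adjusted over the list alone, with AREG, GREB1, EGR3 (2.06 ± 0.18) and TFF1 foremost. Of 19 estrogen-repressed genes 14 fell and 2 rose, also adjusted over the list alone, among them the growth-inhibitory cyclin CCNG2 (-1.70 ± 0.08), the pro-apoptotic BIK (-1.39 ± 0.13) and TP53INP1 (-1.10 ± 0.10). Of 39 cell cycle genes 29 rose and none fell (33 adjusted over the list alone), including CDC20 (1.02 ± 0.12), CDC6 (0.81 ± 0.07), CDT1 (0.76 ± 0.06) and AURKA (0.69 ± 0.09). Of 22 genes of the unfolded protein and integrated stress response 11 rose and 1 fell, with ASNS (0.81 ± 0.07) and TRIB3 (0.69 ± 0.09) at the top. Interferon response genes shifted down, 15 of 29 falling and 4 rising (18 and 5 adjusted over the list alone), with RSAD2 (-0.94 ± 0.07), ISG15 (-0.84 ± 0.12) and PSMB9 (-0.83 ± 0.10). Of 22 luminal markers 13 fell and 2 rose, with MLPH (-0.90 ± 0.09) among the former and TFF3 (1.40 ± 0.12) and TFAP2C (0.84 ± 0.12) the latter. With an estimated correlation none of these lists was called: the adjusted p = 0.077 for the induced targets, p = 0.15 for the repressed genes, the cell cycle and the luminal markers, and p = 0.24 for the stress response and interferon lists.

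In all, limma called 8870 of 21236 genes with E2, 4313 higher and 4557 lower, and 107 and 522 of these changed at least 2-fold. Without replicate 2 the count was 4499. With median centring 5257 were higher and 1994 lower.

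The second question was what 4-OHT changed against vehicle. SPINK4, a secreted protease inhibitor (5.84-fold, 2.55 ± 0.18), FHL2, a transcriptional cofactor (5.56-fold, 2.48 ± 0.10), ATP4A, the catalytic subunit of the gastric proton pump (2.24 ± 0.15), the stress cytokine GDF15 (1.78 ± 0.11) and NKAIN1 (1.74 ± 0.09) rose most. The Cy5 signal of vehicle was above background on 6 of 15 arrays for SPINK4 and on 1 for ATP4A. MUCL1, a secreted mucin-like protein, fell 7.06-fold (-2.82 ± 0.09) and the dynein chain DNAI3 fell by 2.28 ± 0.41 with Cy3 signal on 1 of 3 arrays. KIR2DS4, F3 and the adhesion molecule L1CAM were below background in Cy3 and at least 5.35-fold, 4.35-fold and 3.63-fold lower. KIR2DS4 was so with every treatment and F3 with all but 4-OHT+ICI, and DNAI3 had Cy3 signal on at most 1 of 3 arrays of any treatment. In these genes Cy5 was above background on all 15 arrays, so dye and 4-OHT cannot be told apart. L1CAM had Cy3 signal on all 3 ICI arrays.

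Of the panel, IGFBP4 (1.62 ± 0.15), PDZK1 (1.57 ± 0.10), TFF1 (1.42 ± 0.30), CCND1 (0.67 ± 0.11) and MYC (0.36 ± 0.07) rose, and IGF1R (-0.80 ± 0.10) and ESR1 (-0.73 ± 0.06) fell. CXCL12 rose by 0.23 ± 0.05, a call that ended without replicate 2 (0.21) and with median centring (0.00). GREB1 (0.89 ± 0.34), PGR (-0.32 ± 0.19), FOS (-0.19 ± 0.17) and MKI67 (0.17 ± 0.09) were not called. With the replicate block limma called GREB1 and MKI67 (adjusted p = 0.035 and 0.031), again without the spread between vehicle samples.

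Of 39 estrogen-induced targets 19 rose and 9 fell with 4-OHT (20 and 9 adjusted over the list alone). Of 19 estrogen-repressed genes 12 fell, among them CCNG2 (-0.69 ± 0.08, not called with median centring at -0.32) and PIK3IP1 (-0.66 ± 0.09), and 2 rose, with the same counts adjusted over the list alone. One of the latter was NDRG1 (0.71 ± 0.17), a call that ended without 4-OHT replicate 1 (0.53) and without replicate 3 (0.75). Of 39 cell cycle genes 24 rose and 1 fell (26 and 1 adjusted over the list alone), including the mitotic kinesin KIF11 (0.71 ± 0.10), CDT1 (0.69 ± 0.06) and CDC20 (0.65 ± 0.12). The estimated correlation gave these 3 lists adjusted p = 0.31, p = 0.21 and p = 0.21, so their calls were lost. Of 22 hypoxia and glycolysis genes 16 rose and 1 fell, including LDHA (0.82 ± 0.12), PFKFB4 (0.79 ± 0.06) and HK2 (0.71 ± 0.10), while the prolyl hydroxylase EGLN3 fell (-0.94 ± 0.11). Interferon response genes fell, 18 of 29 with none rising (21 adjusted over the list alone), including HERC6 (-0.70 ± 0.07), MX1 (-0.70 ± 0.08) and ISG15 (-0.63 ± 0.12). For these lists the adjusted p was 2.7e-05 and 9.0e-07 with the preset correlation, and p = 0.053 and p = 0.058 with an estimated correlation. Cholesterol biosynthesis (9 of 24 rose and 1 fell, MVD 0.58 ± 0.09 and ACAT2 0.52 ± 0.07) and the stress response list (10 of 22 rose and 1 fell, ASNS 0.73 ± 0.07 and TRIB3 0.61 ± 0.09) were called higher, and lost their calls with an estimated correlation (p = 0.30 and p = 0.26). So were NRF2 targets (8 of 19 rose and 4 fell, with the cystine carrier SLC7A11 at 1.05 ± 0.09 and GCLM at 0.80 ± 0.08), whose call ended with the scanner's ratio, with the slide as a term and with an estimated correlation (p = 0.42). Among ribosomal protein genes 5 of 28 fell, which ended with the scanner's ratio and an estimated correlation (p = 0.21). Among markers of other cell types, 3 of 8 measured leukocyte and endothelial genes rose, led by CD68 (0.66 ± 0.09), with a list median of 0.18 but a mean of -0.07, and the call ended with the scanner's ratio and an estimated correlation (p = 0.13).

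For 4-OHT the total was 7746 of 21146 genes, 4001 higher and 3745 lower, with 50 and 283 changed at least 2-fold. Leaving out replicate 2 gave 3235, and median centring gave 6932 higher and 1883 lower.

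The third comparison asked what ICI changed by itself. The fibrinogen genes FGG and FGB fell 7.61-fold and 5.41-fold (-2.93 ± 0.18 and -2.44 ± 0.18), the glutathione transferases GSTA5 and GSTA2 by 2.42 ± 0.19 and 2.34 ± 0.19, and MUCL1 by 2.32 ± 0.09. ALDH1A3, an enzyme of retinoic acid synthesis (3.31-fold, 1.72 ± 0.11), ENTREP1 (1.63 ± 0.12), the cell cycle kinase CDK6 (1.56 ± 0.10), ANXA3 (1.51 ± 0.12) and the transcription factor KLF2 (1.43 ± 0.06) rose. Of the panel, PGR (-2.06 ± 0.19), TFF1 (-1.63 ± 0.30) and ESR1 (-1.27 ± 0.06) fell and MYC rose (0.51 ± 0.07), although MYC was not called with median centring (0.34). ESR1 and MYC went the same way in every ratio to vehicle, so a difference by dye may be part of both values. GREB1 fell by 1.17 ± 0.34, a call that ended without ICI replicate 1 or replicate 1 (-1.04), without ICI replicate 3 (-1.12) and without replicate 2 (-1.33).

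Cell cycle genes fell with ICI, 34 of 39 with none rising (1 rose adjusted over the list alone), with BUB1 (-0.90 ± 0.10), CCNB1 (-0.82 ± 0.10), CCNA2 (-0.81 ± 0.09) and CENPA (-0.80 ± 0.08). This list kept its call with an estimated correlation (adjusted p = 0.044). So did lysosome and autophagy genes, of which 13 of 24 rose, such as PSAP (0.79 ± 0.16) and GABARAPL1 (0.69 ± 0.07). AHR targets also kept theirs, with 6 of 8 rising (7 and 1 lower adjusted over the list alone), including ALDH1A3, UGT1A6 (1.21 ± 0.08) and ALDH3A1 (1.05 ± 0.14). The camera test of these 2 lists gave an adjusted p = 0.020. Estrogen-repressed genes rose, 13 of 19 (16 adjusted over the list alone), including CYP1B1 (0.81 ± 0.13), CCNG2 (0.79 ± 0.08), TP53INP1 (0.78 ± 0.10) and ERBB2 (0.73 ± 0.09), with p = 0.057 at an estimated correlation. NRF2 targets rose in 11 of 19, with TXNRD1 (1.25 ± 0.13) and ABCC3 (1.11 ± 0.09), and 12 of 28 ribosomal protein genes fell, but both calls were lost with an estimated correlation (p = 0.23 and p = 0.057). Also higher by camera alone were the stress response list (12 of 23 rose and 2 fell, ATF3 0.60 ± 0.06), AP-1 and immediate early genes (8 of 20 rose, PLAU 0.79 ± 0.09) and growth factor receptor signalling, of which 8 of 26 rose and 4 fell, the latter including IRS1 (-1.44 ± 0.13) and MET (-0.76 ± 0.06). Their adjusted p was 0.18, 0.33 and 0.18 with an estimated correlation, and the growth factor call also ended with the scanner's ratio and with the normexp model fitted on all spots.

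ICI changed 6939 of 21160 genes, 3596 higher and 3343 lower, 37 and 206 of them at least 2-fold. The count was 3040 with median centring, 2347 with only the ICI arrays, 3332 without replicate 2, 4378 without replicate 1 and 3805 without ICI replicate 1.

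**Figure D1:**
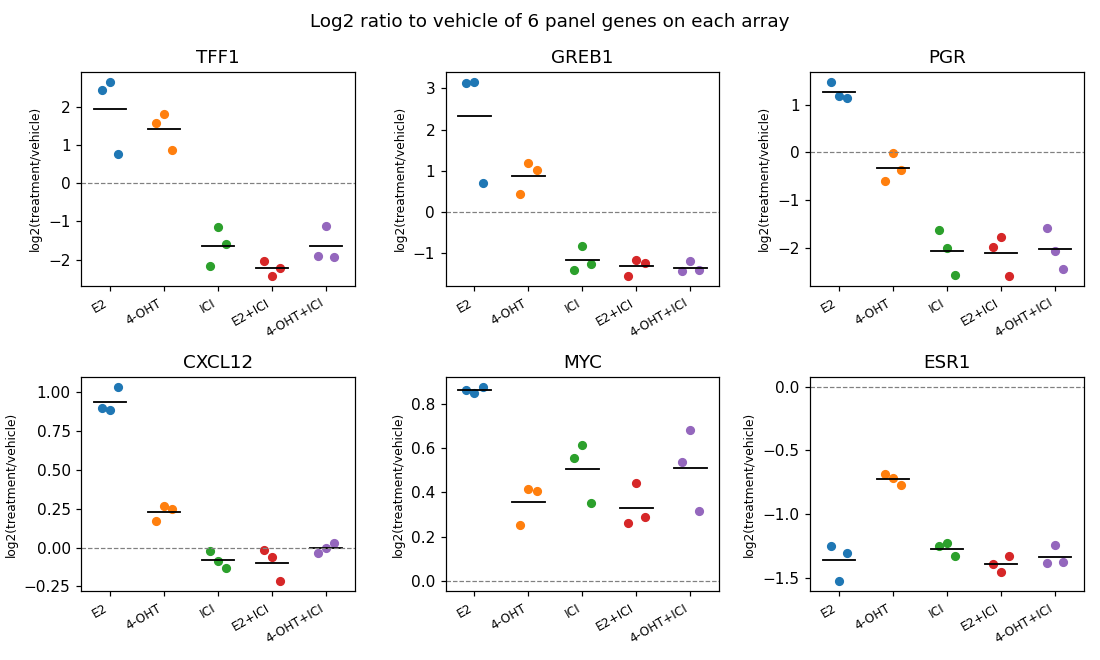
Log2 ratio to vehicle (vertical axis) of 6 ER-related genes on each array, by treatment (horizontal axis). Points are arrays, 3 per treatment, and lines are their means. TFF1 is above 0 on all E2 and 4-OHT arrays and below 0 on all arrays with ICI, and ESR1 is below 0 on all 15 arrays.

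E2 and 4-OHT were compared for the genes they shared. Both raised FHL2 (1.66 with E2 and 2.48 with 4-OHT), TFF1, NKAIN1 (1.40 and 1.74), IGFBP4 and FABP5 (1.93 and 0.77), and both lowered SELENOP, which encodes selenoprotein P (-2.32 and -2.16), and MUCL1 (-1.51 and -2.82). STOX2, C12orf60 and HASPIN had lower values still, but a usable value on only 1 E2 array. The called genes that went the same way numbered 4983 (2436 higher and 2547 lower), where independent lists would give 1606, and 283 went opposite ways, where 1609 would be expected. The correlation across genes was 0.73, against 0.29 in simulated unchanged groups that share the vehicle samples, and genes are not independent replicates. The opposite genes included the kallikrein KLK10 (2.19 with E2 and -1.39 with 4-OHT), the phosphatase PPM1K (1.57 and -1.66), PDLIM3 (1.62 and -1.57), NNMT (0.90 and -1.91) and FGG (1.38 and -1.19), and, the other way, CYP26A1, which degrades retinoic acid (-2.11 and 0.45), TGFBI (-1.86 and 0.29), RDH10 (-1.38 and 0.69), LMCD1 (-1.06 and 0.87) and the chemokine receptor CXCR4 (-1.50 and 0.34). Without replicate 2 the shared count was 1740.

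For E2 and ICI alone, 2155 genes were called in opposite directions, where independent lists would give 1442, and 1294 in the same direction, where 1439 would be expected. Simulated unchanged groups that share the vehicle samples gave 0 opposite genes and at most 3 the same way. Few genes are called in such groups, so these counts set no baseline for sharing. The correlation across genes, which are not independent replicates, was 0.17 (Spearman -0.04), against 0.29 in those groups. FGG, TFF1, FGB (1.1 and -2.44), KLK10 and TFF3 (1.40 and -2.11) rose with E2 and fell with ICI, and CYP26A1, HOXB2, TARP, SELENOP and ENTREP1 (-1.42 and 1.63) did the reverse. The opposite count was 853 with median centring, 861 with only the arrays compared, 767 without replicate 2, 1325 without replicate 3 and 1377 without replicate 1.

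Whether E2 responses depended on ER was addressed by adding ICI to E2. FGG was 22.0-fold lower with E2+ICI than with E2 (-4.46 ± 0.25), TFF1 18.0-fold (-4.17 ± 0.42), FGB 14.6-fold (-3.86 ± 0.25) and KLK10 13.7-fold (-3.77 ± 0.29), and KLK8 was at least 34.4-fold lower. HOXB2 (11.5-fold, 3.52 ± 0.20), CYP26A1 (9.52-fold, 3.25 ± 0.13), ENTREP1 (3.14 ± 0.17), the immune checkpoint ligand VTCN1 (3.12 ± 0.20) and EGLN3 (3.08 ± 0.16) were higher. Of the panel, GREB1 (-3.66 ± 0.48), PGR (-3.38 ± 0.27, with signal on 1 of 3 E2+ICI arrays), PDZK1 (-0.97 ± 0.15) and MYC (-0.53 ± 0.10) were lower and CXCL12 at least 2.15-fold lower. FOS (-1.19 ± 0.24), IGFBP4 (-0.80 ± 0.21), CCND1 (-0.62 ± 0.15) and MKI67 (-0.57 ± 0.13) were lower too, but these calls ended without replicate 2 (-1.04, -0.77, -0.56 and -0.57). IGF1R (-0.33 ± 0.14, called with the replicate block at an adjusted p = 0.039) and ESR1 (-0.03 ± 0.08) were not called.

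Estrogen-induced targets were lower with E2+ICI than with E2 in 26 of 39 and higher in 4 (28 and 5 adjusted over the list alone), including TFF3 (-3.56 ± 0.16), and 15 of 19 estrogen-repressed genes were higher, including CCNG2 (2.40 ± 0.11), BIK (1.87 ± 0.19) and TP53INP1 (1.75 ± 0.14). Cell cycle genes were lower in 36 of 39, with CDC20 (-1.73 ± 0.17), BUB1 (-1.63 ± 0.14) and the mitotic kinase PLK1 (-1.60 ± 0.14), and 16 of 24 lysosome and autophagy genes were higher and 1 lower, with GABARAPL1 (1.75 ± 0.10) and the transcription factor TFEB (1.31 ± 0.16). These 4 lists kept their calls with an estimated correlation (adjusted p = 0.039 for each). Luminal markers (13 of 22 higher and 1 lower, GATA3 1.09 ± 0.14 and MLPH 1.09 ± 0.13) and AHR targets (5 of 8 higher, ALDH1A3 2.94 ± 0.15) were called higher with the preset correlation only (p = 0.12 and p = 0.10 with an estimated correlation). Ribosomal protein genes were called lower with 2 of 28 past the threshold, none adjusted over the list alone (p = 0.21 with an estimated correlation).

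Of the 8870 genes called with E2, 5619 (63.3%) were called the opposite way on adding ICI, where independent lists would give 1618. Both sides hold the E2 arrays, and simulated unchanged groups that share them gave 0 such genes. With nothing changed few genes are called, so the 0 sets no baseline for sharing. The correlation across genes, which are not independent replicates, was -0.69, but -0.61 in those groups. Without replicate 2 the number was 2618, and with median centring 2986. In all 7787 of 21164 genes differed, 4062 higher and 3725 lower, 560 and 334 of them at least 2-fold, and the count was 3951 without replicate 2 and 4208 with median centring.

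Against vehicle, E2+ICI resembled ICI alone: FGG (-3.08 ± 0.18), FGB (-2.76 ± 0.18), CYB5D1 (-2.71 ± 0.38), GSTA1 (-2.69 ± 0.20) and GSTA5 (-2.65 ± 0.19) were lowest, and ENTREP1 (1.72 ± 0.12), ALDH1A3 (1.63 ± 0.11), ANXA3 (1.45 ± 0.12), KLF2 (1.44 ± 0.06) and CDK6 (1.41 ± 0.10) highest. TFF1 (-2.22 ± 0.30), PGR (-2.11 ± 0.19, with Cy3 signal on 1 of 3 arrays) and ESR1 (-1.39 ± 0.06) fell, and GREB1 fell by 1.32 ± 0.34, a call that ended without E2+ICI replicate 1 or replicate 1 (-1.20) and without replicate 2 (-1.39). Among cell cycle genes 35 of 39 fell, such as BUB1 (-0.95 ± 0.10), with an adjusted p of 0.022 at an estimated correlation. AHR targets rose in 7 of 9, with ALDH1A3 foremost, and 1 of the 7, CYP1A1, had a usable value on only 1 array. Lysosome and autophagy genes rose in 12 of 24, and 10 of 28 ribosomal protein genes fell. The camera test with an estimated correlation kept these 3 calls (adjusted p = 0.020, p = 0.020 and p = 0.043). It lost 4 lists called higher: the estrogen-repressed genes (12 of 19 rose), the stress response (10 of 22), AP-1 and immediate early genes (11 of 20 rose and 1 fell) and NRF2 targets (10 of 19). Their camera adjusted p was 0.057, 0.18, 0.18 and 0.26. In total 6463 of 21239 genes were called, 3329 higher and 3134 lower, of which 4835 were among those ICI changed in the same direction, where independent lists would give 1050 and simulated unchanged groups that share the vehicle samples at most 2. That last count sets no baseline for sharing, as few genes are called in such groups. Across genes, which are not independent replicates, the correlation was 0.88, against 0.30 in those groups. Counts were 3896 with the normexp model fitted on all spots, 2346 without replicate 2, 3580 without replicate 3, and 3977, 4062 and 4069 without E2+ICI replicate 1, 2 and 3. With median centring 4122 were higher and 1044 lower.

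The same question for 4-OHT was addressed by adding ICI to it. TFF1 (8.39-fold, -3.07 ± 0.42), SPINK4 (-2.79 ± 0.25, with signal on 1 of 3 4-OHT+ICI arrays), SUSD3 (-2.43 ± 0.12), RAMP1, a partner of calcitonin family receptors (-2.36 ± 0.21), and CA12, a carbonic anhydrase (-2.32 ± 0.23), were lower with 4-OHT+ICI than with 4-OHT. SELENOP (6.73-fold, 2.75 ± 0.18), ENTREP1 (2.28 ± 0.17), ARHGEF37 (2.17 ± 0.14) and ALDH1A3 (2.16 ± 0.15) were higher, and L1CAM at least 2.24-fold higher. Of the panel, GREB1 (-2.24 ± 0.48, not called without replicate 2 at -2.15), PDZK1 (-1.83 ± 0.15), PGR (-1.70 ± 0.27) and IGFBP4 (-1.36 ± 0.21) were lower. IGF1R was higher (0.85 ± 0.14, not called with median centring at 0.48) and ESR1 lower (-0.61 ± 0.08, not called with trend and robust moderation).

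Cell cycle genes were lower in 35 of 39 (37 adjusted over the list alone), with KIF11 (-1.39 ± 0.14), PLK1 (-1.39 ± 0.14) and BUB1 (-1.26 ± 0.14), 16 of 19 estrogen-repressed genes were higher and 1 lower, with CCNG2 (1.45 ± 0.11) and PIK3IP1 (1.31 ± 0.13), and 7 of 8 AHR targets were higher, with UGT1A6 (1.18 ± 0.11). Each kept its call with an estimated correlation (adjusted p = 0.041). Estrogen-induced targets were lower in 22 of 39 and higher in 5, and hypoxia and glycolysis genes lower in 11 of 22 and higher in 4, with LDHA at -1.06 ± 0.16, PFKFB4 at -0.99 ± 0.08 and EGLN3 at 1.86 ± 0.16. Interferon response genes were higher in 10 of 29, with HERC5 (1.00 ± 0.12), and lysosome and autophagy genes in 8 of 24, with GABARAPL1 (1.18 ± 0.10). With an estimated correlation the calls of these 4 lists were lost (p = 0.14, p = 0.096, p = 0.089 and p = 0.068). Growth factor receptor signalling (11 of 26 higher and 4 lower, IRS1 -1.20 ± 0.20 with a usable value on 2 of the 4-OHT arrays, and FGFR1 1.14 ± 0.09) and leukocyte and endothelial markers (3 of 8 lower, CD19 -0.77 ± 0.11 and VWF -0.68 ± 0.10) were also called by camera alone (p = 0.089 and p = 0.096 with an estimated correlation), the latter not with the scanner's ratio, the normexp model fitted on all spots or the slide as a term.

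Of the 7746 genes called with 4-OHT, 3999 (51.6%) were called the opposite way on adding ICI, where independent lists would give 1187 and simulated unchanged groups that share the 4-OHT arrays gave 0. As few genes are called in such groups, the 0 sets no baseline for sharing. The correlation across genes was -0.65, but -0.60 in those groups. Without replicate 2 the number was 1300 and without replicate 3 it was 2308. Altogether 6551 of 21103 genes differed, 3338 higher and 3213 lower, 336 and 212 of them at least 2-fold. The count was 2266 without replicate 2 and 3544 without replicate 3, and median centring gave 1255 higher and 6239 lower.

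Against vehicle, 4-OHT+ICI lowered FGG (-2.70 ± 0.18), MUCL1 (-2.50 ± 0.09), FGB (-2.35 ± 0.18), GSTA5 (-2.28 ± 0.19) and GSTA2 (-2.26 ± 0.19) and raised ALDH1A3 (1.90 ± 0.11), ANXA3 (1.60 ± 0.12), CYP26A1 (1.56 ± 0.09), ENTREP1 (1.53 ± 0.12) and APP (1.52 ± 0.24). PGR (-2.02 ± 0.19), TFF1 (-1.65 ± 0.30) and ESR1 (-1.33 ± 0.06) fell, as did GREB1 (-1.35 ± 0.34, not called without replicate 2 at -1.43). Of 8 AHR targets 6 rose and 1 fell, with UGT1A6 (1.42 ± 0.08) and CYP1B1 (1.30 ± 0.13), a call kept with an estimated correlation (adjusted p = 0.015), as was that of lysosome and autophagy genes, of which 14 of 24 rose (p = 0.015). Other list calls were lost with it. Estrogen-repressed genes rose in 13 of 19, stress response genes in 13 of 23 with 2 falling, AP-1 and immediate early genes in 9 of 20 and NRF2 targets in 10 of 19. Their camera adjusted p was 0.060, 0.12, 0.31 and 0.24. Cell cycle genes fell in 32 of 39 and ribosomal protein genes in 11 of 28, with a camera adjusted p of 0.058 and 0.060. Of 4 measured fibroblast and stromal markers 2 rose, COL5A1 (0.58 ± 0.06) being the larger, with p = 0.24 at an estimated correlation and no call with the slide as a term. In total 7692 of 21242 genes were called, 3752 higher and 3940 lower. The count was 2304 without replicate 2, 4328 without replicate 3, 4311 and 4953 without 4-OHT+ICI replicate 2 and 3, and 3998 with median centring (934 higher and 3064 lower).

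Regulation outside ER was addressed by what E2 or 4-OHT still changed with ICI present. No gene was called between E2+ICI and ICI, or between 4-OHT+ICI and ICI, by limma, and 524 and 362 genes had an unadjusted p under 0.05. With the replicate block the calls were also 0, with 954 and 663 genes under an unadjusted p of 0.05. None of the 8870 E2 calls or the 7746 4-OHT calls was thus called in these comparisons. TFF1 differed by -0.59 ± 0.42 between E2+ICI and ICI and by -0.02 ± 0.42 between 4-OHT+ICI and ICI, PGR, dim with E2+ICI, by -0.05 ± 0.27 and 0.04 ± 0.27, GREB1 by -0.15 ± 0.48 and -0.19 ± 0.48, and ESR1 by -0.12 ± 0.08 and -0.06 ± 0.08. The other panel genes, FOS (-0.25 and -0.03), MYC (-0.18 and 0.01), IGF1R (-0.17 and -0.03), IGFBP4 (0.10 and 0.00), CCND1 (0.09 and 0.02), PDZK1 (-0.06 and -0.12), MKI67 (-0.01 and 0.14) and CXCL12, were not called either, and CXCL12 was below background on all E2+ICI and ICI arrays. In simulated data 42.0% of changes of 0.5 and 91.0% of changes of 1 on the log2 scale were recovered between E2+ICI and ICI, so smaller effects would mostly have been missed. As a set, cell cycle genes were called lower with E2+ICI than with ICI (adjusted p = 0.0091, median -0.09) and AHR targets higher with 4-OHT+ICI than with ICI (adjusted p = 0.033, median 0.19), with no member past the threshold and p = 0.95 and p = 0.38 with an estimated correlation. Members included TYMS (-0.26 ± 0.10) and NUSAP1 (-0.15 ± 0.10), and CYP1B1 (0.49 ± 0.19) and TIPARP (0.21 ± 0.11). Both list calls ended with fry and with the normexp model fitted on all spots. Without replicate 1, 375 genes were called between 4-OHT+ICI and ICI, 8 higher and 367 lower.

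**Figure D2:**
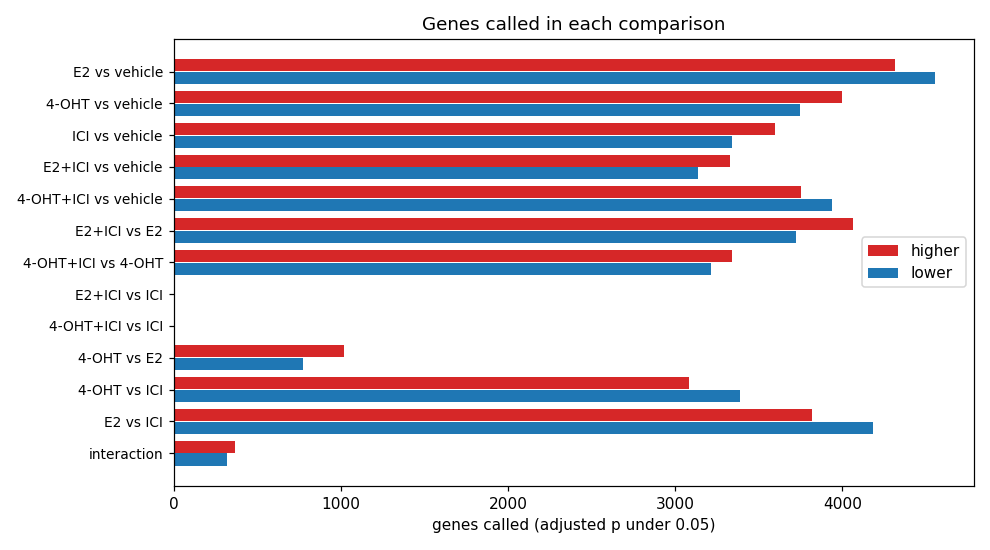
Genes called (horizontal axis, number of genes at an adjusted p under 0.05) in each of the 13 comparisons (vertical axis), with red bars for genes higher and blue bars for genes lower in the first-named treatment. The interaction is the effect of ICI with E2 minus its effect with 4-OHT. E2+ICI against ICI and 4-OHT+ICI against ICI have 0 genes, and E2 against vehicle has most, 8870.

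How 4-OHT and E2 differ was tested directly, at 1 µM and 1 nM, so structure and dose differ together. The kallikreins KLK10 (-3.58 ± 0.29), KLK8 (9.95-fold, -3.31 ± 0.28) and KLK11 (-3.24 ± 0.18), PPM1K (-3.24 ± 0.22) and PDLIM3 (-3.19 ± 0.17) were lower with 4-OHT than with E2. CYP26A1 (5.88-fold, 2.56 ± 0.13), TGFBI (2.15 ± 0.14), the retinol dehydrogenase RDH10 (2.08 ± 0.14) and LMCD1 (1.94 ± 0.11) were higher, and ATP4A at least 6.21-fold higher. Of the panel, PGR (-1.59 ± 0.27), IGF1R (-1.03 ± 0.14) and CXCL12 (-0.71 ± 0.08) were lower, PDZK1 higher (0.80 ± 0.15, not called without replicate 2 at 0.69 or replicate 3 at 0.73) and ESR1 higher (0.63 ± 0.08, not called with trend and robust moderation). GREB1 (-1.45 ± 0.48), FOS (-0.79 ± 0.24) and TFF1 (-0.53 ± 0.42) were not called, and the 95% interval of TFF1 ran from -1.44 to 0.38. The replicate block in limma called GREB1 and FOS (adjusted p = 0.047 and 0.0014).

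Estrogen-induced targets were lower with 4-OHT in 14 of 39 and higher in 4 (16 and 4 adjusted over the list alone), with AREG (6.55-fold, -2.71 ± 0.10), TFF3 (-2.24 ± 0.16), PKIB (-1.86 ± 0.25, not called without replicate 2 at -1.80) and EGR3 (-1.72 ± 0.26). Of 19 estrogen-repressed genes 5 were higher and 2 lower, including CCNG2 (1.01 ± 0.11) and NDRG1 (1.40 ± 0.24, not called without replicate 3 at 1.34). Basal and mesenchymal markers were lower in 7 of 17 and higher in 1, with VIM (-1.22 ± 0.16), SNAI1 (-0.86 ± 0.13) and KRT17 (-0.85 ± 0.10) lower and SPARC (1.06 ± 0.11) higher, and luminal markers were higher in 9 of 22 and lower in 1, with AGR2 (0.76 ± 0.10). Hypoxia and glycolysis genes were higher in 7 of 22 and lower in 1, with ADM (0.84 ± 0.10) and EGLN3 (1.01 ± 0.16, not called without replicate 2 at 0.95). With an estimated correlation none of these held (p = 0.14, p = 0.29, p = 0.14, p = 0.18 and p = 0.14). Lower with 4-OHT by the preset correlation alone were the cell cycle (2 of 39 genes lower, none adjusted over the list alone), growth factor receptor signalling (9 of 26 lower and 3 higher), AP-1 and immediate early genes (5 of 20 lower and 1 higher) and ribosomal proteins (0 of 28 past the threshold). With an estimated correlation camera gave an adjusted p of 0.39, 0.19, 0.41 and 0.19. Cholesterol biosynthesis (3 of 24 higher) and lysosome and autophagy genes (4 of 24 higher and 1 lower) were called higher in the same way, with an adjusted p of 0.34 and 0.18. Of these 6 list calls the cell cycle and AP-1 also ended with fry, and growth factor, AP-1 and ribosomal ones with the scanner's ratio. The slide as a term ended the growth factor, cholesterol and lysosome calls, and the replicate block the growth factor call. The comparison called 1794 of 21104 genes, 1020 higher and 774 lower, 115 and 107 of them at least 2-fold, and 2774 with the replicate block. The count was 645 with median centring, 411 without replicate 2, 823 without replicate 3, 1129 without replicate 1, 1141 without E2 replicate 2 and 1194 without 4-OHT replicate 3.

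The antiestrogens 4-OHT and ICI were compared at the same dose of 1 µM. TFF1 (8.27-fold, 3.05 ± 0.42), RAMP1 (2.60 ± 0.21) and SUSD3 (2.41 ± 0.12) were higher with 4-OHT, and SPINK4 and ATP4A at least 10.6-fold and 5.92-fold higher. SELENOP (7.81-fold, -2.97 ± 0.18), ENTREP1 (-2.39 ± 0.17), CYP4B1 (-2.20 ± 0.15) and STON1 (-2.20 ± 0.17) were lower, and L1CAM at least 1.91-fold lower. Of the panel, GREB1 (2.05 ± 0.48, not called without replicate 2 at 2.06), PGR (1.74 ± 0.27), PDZK1 (1.72 ± 0.15), IGFBP4 (1.36 ± 0.21), CCND1 (0.57 ± 0.15, not called without replicate 2 at 0.59) and ESR1 (0.55 ± 0.08, not called with trend and robust moderation) were higher with 4-OHT and IGF1R lower (-0.87 ± 0.14, not called with median centring at -0.59). Of 39 cell cycle genes 36 were higher, such as BUB1 (1.30 ± 0.14) and CDC20 (1.23 ± 0.17), and 16 of 19 estrogen-repressed genes were lower and 1 higher, such as CCNG2 (-1.48 ± 0.11) and BTG2 (-1.27 ± 0.09). AHR targets were lower in 5 of 8, with ALDH1A3 (-1.98 ± 0.15) and UGT1A6 (-0.98 ± 0.11). With an estimated correlation the adjusted p = 0.0503 by camera for these 3 lists lay just past the threshold. Estrogen-induced targets were higher in 22 of 39 and lower in 5, with CA12 (2.29 ± 0.23), hypoxia and glycolysis genes higher in 10 of 22 and lower in 4, with EGLN3 at -1.93 ± 0.16 and LDHA at 1.19 ± 0.16, and interferon response genes lower in 12 of 29, with HERC5 (-1.14 ± 0.12). Lysosome and autophagy genes were lower in 8 of 24, with GABARAPL1 (-1.12 ± 0.10). These calls were lost with an estimated correlation (p = 0.12 for the first and p = 0.082 for the others), as were those of the growth factor receptor list (11 of 26 lower and 4 higher) and the leukocyte and endothelial list (3 of 8 higher), with p = 0.100 and p = 0.082. A total of 6472 of 21076 genes were called, 3084 higher and 3388 lower. Without replicate 2 the count was 2791 and without replicate 3 it was 3937, and median centring gave 4583 higher and 1381 lower.

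E2 was also set against ICI, a steroid with the ring system of E2 and a long side chain, at doses of 1 nM and 1 µM. FGG (19.8-fold, 4.31 ± 0.25), KLK8 (3.92 ± 0.28, with signal on 1 of 3 ICI arrays), TFF1 (3.58 ± 0.42), FGB (3.54 ± 0.25) and KLK10 (3.53 ± 0.29) were higher with E2, and CYP26A1 (10.4-fold, -3.38 ± 0.13), HOXB2 (-3.35 ± 0.20), SELENOP (-3.12 ± 0.18), ENTREP1 (-3.05 ± 0.17) and ALDH1A3 (-3.03 ± 0.15) lower. Cell cycle genes were higher in 36 of 39, with CDC20 (1.60 ± 0.17), estrogen-induced targets higher in 27 of 39 and lower in 4, with TFF3 (3.51 ± 0.16), estrogen-repressed genes lower in 14 of 19, with CCNG2 (-2.49 ± 0.11), and lysosome and autophagy genes lower in 11 of 24 and higher in 2, with GABARAPL1 (-1.57 ± 0.10). Each of these lists had an adjusted p of 0.039 by camera at an estimated correlation. Luminal markers were lower in 14 of 22 and higher in 1, with MLPH (-1.16 ± 0.13, not called with median centring at -0.50), and AHR targets lower in 4 of 8, with UGT1A6 (-1.32 ± 0.11), calls lost with an estimated correlation (p = 0.13 and p = 0.084). Interferon response genes (9 of 29 lower and 1 higher) and ribosomal protein genes (7 of 28 higher, 1 adjusted over the list alone) lost their calls too. Camera gave them an adjusted p of 0.39 and 0.28. GREB1 (3.50 ± 0.48), PGR (3.33 ± 0.27) and PDZK1 (0.91 ± 0.15) were higher and CXCL12 at least 2.13-fold higher. FOS (0.93 ± 0.24), IGFBP4 (0.90 ± 0.21), CCND1 (0.71 ± 0.15) and MKI67 (0.56 ± 0.13) were higher too, calls that ended without replicate 2 (0.75, 0.77, 0.66 and 0.57), and MYC (0.36 ± 0.10) was not called without replicate 1 (0.38), replicate 3 (0.27) or ICI replicate 3 (0.28). IGF1R (0.16 ± 0.14) was not called, nor was ESR1 (-0.09 ± 0.08), which fell against vehicle with either compound. As ESR1 fell in all ratios to vehicle, dye and treatment cannot be told apart in the common part of that fall. The comparison called 8001 of 21107 genes, 3818 higher and 4183 lower, and 4219 without replicate 2, and median centring gave 4211 higher and 1743 lower.

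Whether ICI changed E2 and 4-OHT samples differently was tested on the difference of the differences. The effect of ICI with E2 minus that with 4-OHT was negative for KLK10 (-3.77 ± 0.41), KLK11 (-3.45 ± 0.26), PDLIM3 (-3.23 ± 0.24), NNMT (-3.09 ± 0.20), AREG (-2.87 ± 0.14) and KLK8. KLK11 had signal on 1 of 3 E2+ICI arrays, and KLK8 was below background on all 3. With ICI, KLK10, KLK8, KLK11 and AREG were lower in E2 samples and not called in 4-OHT samples (-3.77 and 0.00 for KLK10, -2.60 and 0.27 for AREG), and PDLIM3 and NNMT were lower in E2 samples and higher in 4-OHT samples. The difference was positive for TGFBI (2.21 ± 0.19), CYP26A1 (2.14 ± 0.19), RDH10 (1.98 ± 0.20), FGD6 (1.79 ± 0.13) and ATP4A. ICI raised CYP26A1 with both (3.25 and 1.11), TGFBI and RDH10 with E2 alone (2.56 and 1.60), and FGD6 with E2 (0.37) while lowering it with 4-OHT (-1.41). ATP4A was lower with 4-OHT+ICI than with 4-OHT and below background on all arrays with E2, and its call ended without replicate 2. Limma called 688 of 21071 genes, 368 higher and 320 lower, 1406 with the replicate block and 1287 with the slide as a random block. The count was 354 with median centring (255 higher and 99 lower), 54 without replicate 2, 224 without replicate 3, 441 without E2 replicate 2 and 444 without 4-OHT+ICI replicate 2.

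In these differences vehicle and dye cancel, so the changes that ICI made in E2 and 4-OHT samples could be compared without them. This overlap was chosen after the data were seen. Both changes hold ICI's own effect against vehicle, which the baselines below leave out. FGG rose with E2 (1.38) and fell with 4-OHT (-1.19) against vehicle, but went the same way here (-4.46 and -1.52). With ICI alone it was -2.93. Counts, correlation and ratios are thus not of the E2 and 4-OHT responses alone. Of genes called in both, 4516 went the same way, where independent lists would give 1195, with a correlation across genes of 0.72 against -0.01 in simulated unchanged groups. They included SELENOP (3.05 and 2.75), ENTREP1 (3.14 and 2.28), HOXB2 (3.52 and 1.84), TFF1 (-4.17 and -3.07) and TFF3 (-3.56 and -1.36). Another 78 went opposite ways, where 1193 would be expected, including PDLIM3 (-2.18 with E2 and 1.05 with 4-OHT), NNMT (-1.36 and 1.73), ARSJ (-0.52 and 1.49), FGD6 (0.37 and -1.41) and CXCR4 (1.27 and -0.49). Among the 334 genes at least 2-fold higher with E2 than with E2+ICI, the median ratio of the 4-OHT to the E2 effect was 0.68 (quartiles 0.39 and 0.83), and among the 560 at least 2-fold lower it was 0.65 (0.46 and 0.80). Both sets were chosen by the size of the E2 effect, which is also the divisor, so the choice can draw the ratio down. No set chosen by the 4-OHT effect was examined. A common dose was not tested.

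**Figure D3:**
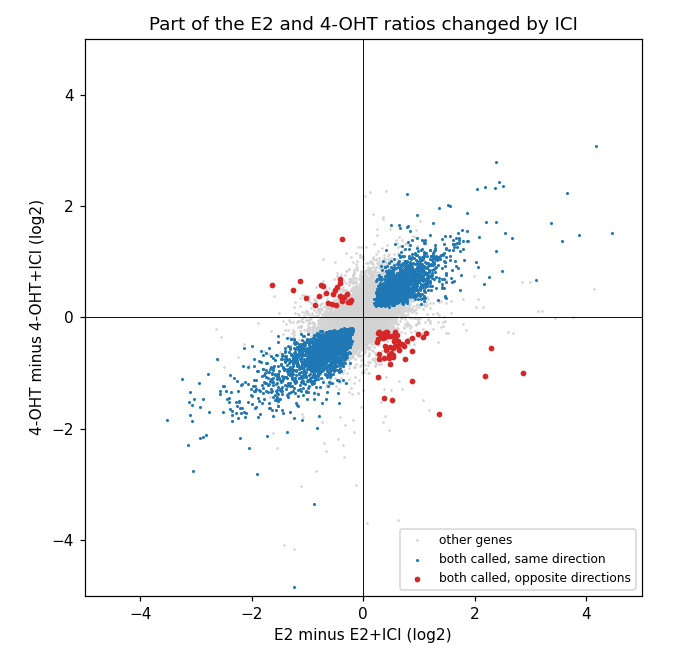
Part of the 4-OHT response that ICI changed (vertical axis, 4-OHT minus 4-OHT+ICI, log2) against that of the E2 response (horizontal axis, E2 minus E2+ICI, log2), each point a gene. Blue points are the 4516 genes called in both in the same direction, red points the 78 called in opposite directions and grey points all others. The correlation across genes is 0.72. Both differences also hold the effect of ICI itself.

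Apoptosis regulators were called in none of the 13 comparisons: of 24 measured, 6 rose and 7 fell with E2, 8 rose and 7 fell with 4-OHT, and 6 rose and 3 fell with ICI. Fibroblast and stromal markers were called with 4-OHT+ICI against vehicle alone, and the leukocyte and endothelial list with 4-OHT against vehicle, with 4-OHT+ICI against 4-OHT and with 4-OHT against ICI. Each of these list calls was lost with an estimated correlation.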

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

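ICI changed E2 and 4-OHT samples differently in 688 genes, tested as the effect of ICI with E2 minus its effect with 4-OHT. Each gene here passed that test, and a negative value means that the effect of ICI with E2 lay below its effect with 4-OHT. Some moved in opposite directions, or with only 1 of the compounds. Others moved the same way with both by different amounts, such as TFF3 (-3.56 with E2 and -1.36 with 4-OHT). The genes that passed included KLK10 (-3.77), KLK11 (-3.45), PDLIM3 (-3.23) and NNMT (-3.09) at one end and TGFBI (2.21), CYP26A1 (2.14), RDH10 (1.98) and FGD6 (1.79) at the other. ATP4A (2.14) was below background on all arrays with E2, and KLK8 (-3.65) and CXCL12 (-0.81) on all E2+ICI arrays, so the size of these differences is not measured and they have no place in the order. PGR and KLK11 had signal on 1 of 3 E2+ICI arrays. Of the panel they were PGR (-1.68), IGF1R (-1.17), PDZK1 (0.86), MYC (-0.69) and ESR1 (0.58). From the gene lists they were the ER targets AREG (-2.87), TFF3 (-2.20) and PKIB (-2.06), the estrogen-repressed BIK (1.08) and CCNG2 (0.95) and, in the other direction, KLF4 (-0.67), the stress response gene ATF3 (-0.47), the luminal marker AGR2 (0.85), the basal and mesenchymal markers VIM (-1.16), SPARC (1.02), SNAI1 (-0.93) and KRT17 (-0.77), and the hypoxia and glycolysis genes EGLN3 (1.21), ADM (0.73) and SLC2A1 (0.73). Of these 31 genes 20 were not called without replicate 2, 14 without replicate 3, 7 without replicate 1 and 8 with median centring. Leaving out a single array ended the call of ATF3 for 11 arrays, BIK for 9, PDZK1 for 7 and PGR for 6. Trend and robust moderation ended ATF3, PGR and ESR1, loess with scaling ATF3 and ESR1, the mean of probes ATF3 and CCNG2, no filter on dim probes ATF3, BIK and PDZK1, and the normexp model fitted on all spots BIK and PGR. PDZK1 also ended with the scanner's ratio and the authors' series table, ATF3 with only the arrays compared and CCNG2 without the spots marked for background. The list shifts were lost with an estimated correlation (adjusted p = 0.17 for ER targets, luminal, basal and hypoxia lists, 0.42 for estrogen-repressed genes, 0.34 for the cell cycle, 0.43 for the stress response and 0.28 for ribosomal proteins).

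Both tests of genes called the same way in all 5 ratios to vehicle were chosen before their results were seen. If they came from single probes with a dye preference, other probes of the same genes should not share the direction, and 112 of 143 did (78.3%, 95% interval 70.7 to 84.8), which leaves the question open since a dye effect can lie in the transcript. If they came from dim Cy3 spots, few should be bright in both dyes, but of the 557 genes 509 (91.4%) were bright in both on all arrays, which argues against it. Among the 16490 bright genes independent lists would give 8.75 of them, though the ratios share their vehicle samples. Simulated unchanged groups that share them gave at most 1 gene higher and 2 lower in all 5 ratios, but few genes are called where none is changed. GSTA1, GSTA2 and MUCL1 fell with every treatment. All 3 were lower with E2+ICI than with E2 (-1.26, -1.21 and -0.96), where dye cancels, so that part is not due to dye. The part common to all treatments may be a response or a difference by dye. The same holds for the part common to all treatments in ESR1, which fell in all 5 ratios, and in MYC, which rose in all 5.

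For the absence of calls with ICI present, the tests of a small spread effect and of missing E2 were chosen after the result was seen. For genes called and at least 2-fold apart between E2 and ICI, lack of precision is argued against by the interval of E2+ICI minus ICI. It excluded 0.5 of the E2 to ICI difference in 92.0% of 870 genes, with a median share kept of 0.002. Genes with smaller differences are not covered, and in simulated data 0% of changes of 0.25 on the log2 scale were recovered between E2+ICI and ICI. A small effect spread over many genes stays open, as 2.48% of genes had an unadjusted p under 0.05 (4.52% with the replicate block), within the 1.59% to 12.2% of other splits. That E2 was missing from the E2+ICI dishes cannot be told apart, as 0 genes were called either way.

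For the differences between 4-OHT and E2, the test of a single scale factor was chosen after the result was seen. If 4-OHT were a weaker E2, by a factor of 0.65, at most 5 genes would be called in opposite directions in 20 simulations, and 78 were, PDLIM3 and NNMT among them. The factor came from genes chosen for a large difference between E2 and E2+ICI. The simulation scaled the differences to samples with ICI, which also hold ICI's own effect, and not the ratios to vehicle. If 4-OHT acted apart from the receptor, its part of the difference should remain with ICI. The median share kept was -0.0088 (quartiles -0.14 and 0.12, 1788 genes). The difference also holds what E2 did, which ICI can remove. A low share thus does not decide the question for genes that E2 moved. A median also speaks only for most of these genes and leaves such action on a minority open. In limma, 1149 of 21171 genes had an unadjusted p under 0.05 between 4-OHT+ICI and E2+ICI, and 1713 with the replicate block. Both are shares above 0.05, though 0 genes were called in this comparison, which was added after the data were seen. Signals near background are argued against for 70 of the 78 genes (89.7%), which were bright in both dyes on all arrays. Most genes were bright in this way, 16490 of 21369, so the share itself sets the 78 little apart.

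Grouping the arrays in other ways that part the same pairs gives 4 splits per comparison, too few for a share under 0.05. The real split of E2 and vehicle called 8870 genes and the highest other 113, and no other split of E2+ICI and E2 called any. For 4-OHT+ICI and ICI the real split called 0 and another, ICI replicates 2 and 3 with 4-OHT+ICI replicate 1 against the rest, called 891, a difference among samples that does not follow the slides.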

How the results depend on the processing

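Limits included 3 replicates, dyes never exchanged and a background model that failed on 1 array and was refitted after results had been seen. Simulated ratios to vehicle held a larger share of false calls than the threshold allows. Median centring and the estimated correlation also moved many results. The cause of the changes below was not tested. Named genes kept their result in 13758 of 14373 checks, 516 were weaker and 2 turned direction, CXCL12 between 4-OHT+ICI and 4-OHT (0.028) and ULK1 between 4-OHT and ICI (0.12), both with median centring. Counts by setting were as follows. Median centring: ICI 3040, 4-OHT+ICI 3998, E2+ICI against E2 4208, 4-OHT against E2 645, the difference of differences 354, reversal of E2 calls 2986, E2 and ICI opposite 853. At least 2-fold: E2 629, 4-OHT 333, ICI 243, E2+ICI 322, 4-OHT+ICI 343, E2+ICI against E2 894, 4-OHT+ICI against 4-OHT 548, 4-OHT against E2 222, 4-OHT against ICI 488, E2 against ICI 873, the difference of differences 207. Replicate block: 4-OHT against E2 2774, the difference of differences 1406 (1287 with the slide as a random block). Normexp on all spots: E2+ICI 3896. Only the arrays compared: ICI 2347, E2 and ICI opposite 861. Of 234 list tests 96 were called, and 20 with an estimated correlation. Leaving out arrays gave, against vehicle, 4499 to 7755 for E2, 3235 to 6854 for 4-OHT, 3332 to 5742 for ICI, 2346 to 5205 for E2+ICI and 2304 to 7731 for 4-OHT+ICI. It gave 3951 to 7422 for E2+ICI against E2, 2266 to 6799 for 4-OHT+ICI against 4-OHT, 0 to 0 for E2+ICI against ICI, 0 to 375 for 4-OHT+ICI against ICI, 411 to 1633 for 4-OHT against E2, 2791 to 5757 for 4-OHT against ICI, 4219 to 7723 for E2 against ICI and 54 to 913 for the difference of differences. Reversal ranged from 2618 to 5938 for E2 and 1300 to 4209 for 4-OHT, and the overlaps from 1740 to 4712 (E2 and 4-OHT) and 767 to 2138 (E2 and ICI).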

Other observations

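The gene families here were chosen after the data were seen. Of 8 measured kallikreins, secreted serine proteases, 6 rose with E2, KLK8 (3.07), KLK10 (2.19), KLK11 (2.18), KLK12, KLK5 and KLK7, and 3 fell with 4-OHT, KLK10 (-1.39), KLK11 (-1.07) and KLK7. KLK7 was below background in vehicle on all arrays and KLK12 and KLK5 on most, so their values are left out, and the fall of KLK7 with 4-OHT did not appear in the scanner's ratio. Adding ICI lowered 5 of them in E2 samples and none in 4-OHT samples. The 3 fibrinogen chains FGA (1.01), FGB (1.1) and FGG (1.38) rose with E2 and fell with 4-OHT (-0.89, -0.87 and -1.19) and with ICI (-1.73, -2.44 and -2.93). All 5 alpha class glutathione transferases fell in every ratio to vehicle, and none differed between 4-OHT and E2. Adding ICI lowered 4 of them in E2 samples and 3 in 4-OHT samples, and 3 were higher with E2, and with 4-OHT, than with ICI.

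Of 6 HOXB genes, 4 fell with E2, HOXB2 (-2.58), HOXB3 (-1.38), HOXB6 (-0.73) and HOXB4 (-0.54), and the same 4 with 4-OHT (-0.95, -0.76, -0.57 and -0.44), and ICI raised all 4 with either. Another rose, HOXB9 with E2 (0.26) and HOXB7 with 4-OHT (0.44). Among 11 genes of retinoid metabolism 4 rose and 5 fell with E2, where the fall of CRABP2 turned direction with median centring, and 5 rose and 1 fell with 4-OHT. Of them CYP26A1 fell with E2 (-2.11) and rose with 4-OHT (0.45), as did RDH10 (-1.38 and 0.69), while ALDH1A3 fell with E2 (-1.30) and was not called with 4-OHT (-0.26).

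E2+ICI and 4-OHT+ICI were also compared, an addition made after the data were seen: limma called 0 of 21171 genes, with 1149 at an unadjusted p under 0.05, and 0 with the replicate block (1713). Cy5 signals of the same vehicle sample on different arrays correlated across probes at a median of 0.994 (lowest 0.976), and those of different vehicle samples at 0.977. Of 71 named genes with several probes, 1 had probes in opposite directions beyond 0.5 with ICI against vehicle, L1CAM (-0.52 and 0.94), and none in the other 5 comparisons examined.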
